A study of Rattus norvegicus with 12 samples.

How the data were processed

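Poly(A)-selected RNA from brain tissue of Sprague-Dawley rats was sequenced as strand-marked paired-end libraries, per the labels' protocols. The labels list 12 samples in 3 groups of 4: restrained rats without electroacupuncture (control), rats with middle cerebral artery occlusion and reperfusion that were restrained only (model), and rats with the same operation that received electroacupuncture at 4 points of the Lung Meridian (electroacupuncture). The labels name no operation for the control group and no brain region or side. The library adapters carried unique molecular identifiers, per the labels, but whether these were used to remove duplicate reads is not given in the sources used here.

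The deposited table holds expected counts (estimated read counts per gene with up to 2 decimals) for 18804 rows and 11 columns. It carries no normalization: column totals differ, from 8668140 to 11920744. Between 70.5% and 72.1% of the values in a column were whole numbers. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used, and the notes give neither their roles nor their order. Which tool made the fractional estimates, and the genome build, are not given in the sources used here. No genomic coordinates are printed for that reason. How reads that match more than 1 gene copy were counted is not given in the sources used here, so values of near-identical genes are uncertain.

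Column names identified the group of each column but not the sample: 4 columns for the model, 4 for electroacupuncture and 3 named as sham-operated, which were taken as the control group because the labels hold no other unoperated or untreated group. The control group therefore has 3 columns for 4 labelled samples. No column was left unused. The 4 symbols that stood on 2 rows were summed, which left 18800 symbols, and values were rounded to whole numbers. Of the symbols, 16024 are current names in the RefSeq annotation of assembly GRCr8, 622 are older synonyms there and 2154 had no match; all were kept under the names in the file.

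Before any group was tested, the columns were compared with each other by a chi-square statistic per gene, over genes with a summed count of at least 20 in the pair. In 3 pairs of columns of the same group, the median squared difference was 1.34 to 1.4 times the sampling variance. The other 12 pairs within a group lay between 4.75 and 26.5 times, and the 40 pairs between groups between 3.63 and 29.4 times. Pairs under 2 times the sampling variance were treated as repeat measurements of 1 sample, and their counts were summed. This left 8 samples: control A, B and C, model A and B, and electroacupuncture A, B and C. Model A, model B and electroacupuncture B each combine 2 columns. This choice was made after seeing how alike the columns were, and before any group comparison was run. The design fixed beforehand had assumed that all 12 labelled samples would enter as separate libraries, so a fit of all 11 columns as separate libraries is given beside the results. Nothing in the sources states that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

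Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, TMM scaling, the default expression filter by group, robust dispersion). All 8 samples of the 3 groups entered 1 fit, and 15487 genes passed the filter. The fit had 5 residual degrees of freedom and a common biological coefficient of variation of 36.8%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic. CPM values were computed with TMM scaling. Totals per sample ran from 9335913 to 23835724, so counting error is small against the spread between samples except for genes under about 1 CPM.

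For brain cell types, injury responses and synaptic functions, 32 gene lists were fixed before the data were examined, and the 31 with at least 4 tested members were tested with camera in limma 3.58.1 (log2 CPM with a prior count of 2, inter-gene correlation preset at 0.01, Benjamini-Hochberg over the lists of a comparison). The list of mitochondrially encoded genes had no member in the table. Each list's calls were also counted with p adjusted over the list alone. Camera was repeated with an estimated correlation, and fry was run for directional and mixed changes. A further 5 lists of brain region markers were chosen after the data had been seen, from textbook knowledge. Their levels are given as descriptions, without a group test.

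Genes named in the text follow a rule fixed before the data were examined. It takes, for model against control and electroacupuncture against model, the 8 genes up and the 8 down with the largest log2 fold change among called genes with a mean of at least 1 CPM, an annotated symbol and no overlap between groups. It adds up to 3 members with the smallest unadjusted p in each list described, and 8 genes called in opposite directions in both comparisons. The first part yielded 1 gene and the last none. Genes outside the rule are named as such. Some genes that the rule takes are not reported here.

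The scripts were tested on simulated counts drawn from the samples' own means and library sizes with 200 genes changed. In the simulation of model against control, over 15487 genes, 6% of genes changed 2-fold were called, 59.7% of those changed 4-fold and 83.3% of those changed 8-fold, with 10 unchanged genes called. For electroacupuncture against model the shares were 6%, 62.7% and 90.9%, with 11 unchanged genes called. For electroacupuncture against control they were 9%, 65.7% and 83.3%, with 7 unchanged genes called. Changes of 2-fold in single genes were thus mostly below what this design detects. For the list test, the myelin list was lowered 2-fold in the simulated model samples, with genes drawn independently of each other. Camera with the preset correlation found it (adjusted p = 2.08e-09) and called 1 unchanged list. With an estimated correlation camera missed it (adjusted p = 0.063), so with independent genes a list that fails there may still hold a 2-fold change. In the data the estimated correlation was 0.845 for microglia, 0.688 for myelin and -0.097 for GABAergic neurons. The simulation therefore does not show how either setting performs on lists whose members move together.

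The alternatives fixed beforehand were DESeq2 1.42.0, DESeq2 size factors, total counts only, no filter, a filter of at least 10 CPM in at least 4 samples, only the 2 groups compared, a minimum absolute log2 fold change of 1, an adjusted p under 0.1, each sample left out in turn, and the set tests named above with camera on quantile-normalized values. Added after seeing the data were all 11 columns as separate libraries, the same with the column number as a replicate block, 1 column of each near-identical pair, the mean in place of the sum of each pair, and the leave-one-out runs of the gene lists and of their mean levels, the hippocampal list without Prox1, the pan-neuronal list without Gap43 and the covariance of the log2 fold changes with 1 sample left out.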

Results

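Messenger RNA was profiled by RNA sequencing in brain tissue of rats from 3 groups: restrained controls, rats with cerebral ischemia-reperfusion made by middle cerebral artery occlusion (the model, which blocks and then reopens a large artery of the brain), and rats with the same operation treated with electroacupuncture (needles carrying a weak current) along the Lung Meridian of the foreleg. The study's title places the treatment in the context of synaptic plasticity. The deposited table has 11 columns of estimated gene counts, 3 for the controls and 4 for each other group. In 3 pairs of columns of 1 group, the counts differed by little more than sampling noise, with a median squared difference of 1.34 to 1.4 times the sampling variance and 10.2% to 11.2% of genes at a chi-square p under 0.05. These pairs were each counted as 1 sample, so the comparisons rest on 3 control, 2 model and 3 electroacupuncture samples. Total counts per sample ranged from 9335913 in control B to 23835724 in electroacupuncture B.

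**Figure D1:**
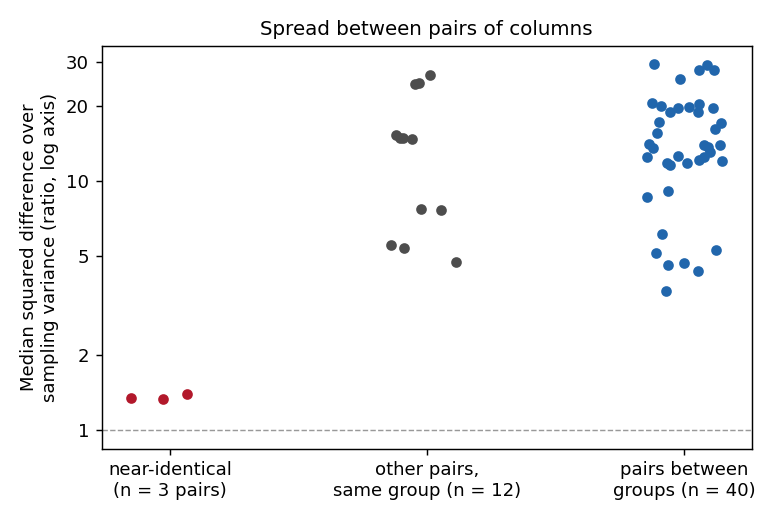
Each point is 1 pair of deposited columns, and the vertical log axis gives the median squared count difference over genes divided by the sampling variance (dashed line at 1). The 3 near-identical pairs lie between 1.34 and 1.4, the 12 other pairs within a group between 4.75 and 26.5, and the 40 pairs between groups between 3.63 and 29.4.

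The samples did not sort by group alone. Electroacupuncture B ranked its genes most like control C (Spearman's rho of 0.987 across genes, which are not independent replicates) and electroacupuncture C most like control A (0.982), while electroacupuncture A was no closer than 0.929 to any sample. The model samples A and B were 0.931 alike, and each was closer to a sample of another group. Model A was most like control B (0.952) and model B most like electroacupuncture B (0.935). Hippocampal markers were low in both model samples and in electroacupuncture A. Prox1, a transcription factor of dentate granule neurons named after its values were seen, stood at 6.38 and 3.83 CPM in model A and B and at 9.8 CPM in electroacupuncture A, against 61.1 to 96 CPM in the other 5 samples. A list of 8 tested hippocampal genes lay at -1.59 and -1.59 (mean log2 difference from the control mean) in model A and B and at -1.18 in electroacupuncture A, against -0.05 and -0.29 in electroacupuncture B and C. Prox1 is 1 of these 8, and the other 7 lay at -1.31, -1.22 and -0.93 in model A, model B and electroacupuncture A and at -0.02 and -0.29 in electroacupuncture B and C. Neocortical markers lay at 1.19 and 1.14 in the model samples, and markers of striatal medium spiny neurons at 2.14 in model A and 4.82 in electroacupuncture A. These levels differ along with the groups and stand beside every gene group described here.

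The first comparison, model against control, asks what the operation did to brain gene expression. Camk2d, the delta chain of calcium/calmodulin-dependent kinase II, rose 8.39-fold, from 17.1 ± 2.23 CPM (SD, n = 3) in controls to 143 ± 15.2 CPM (SD, n = 2) in the model (log2 fold change 3.07, SE 0.23, adjusted p = 0.0263, edgeR quasi-likelihood test). It was the only gene of 15487 tested to pass. Its deposited counts are partly fractional estimates, so reads shared with other genes cannot be ruled out, and they were close within both near-identical pairs of model columns. Genes of microglia, of the interferon response, of axon growth and of GABAergic neurons ranked higher in the model as lists, and genes of myelin, the postsynaptic density and mitochondrial respiration ranked lower, each by a set test that assumes nearly independent genes. With an estimated correlation between genes 0 of these 7 lists passed (adjusted p = 0.977 for each). The estimates ran from -0.097 for GABAergic neurons to 0.845 for microglia, against the preset of 0.01.

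Microglia and macrophage genes were higher in estimate for all 16 tested members, 10 of them with both model samples above every control, and the median log2 fold change was 1.09 (camera adjusted p = 0.000503, but adjusted p = 0.977 with an estimated correlation). None passed singly, over all genes or adjusted over the list alone. Tmem119, a microglial surface marker, measured 8.79 ± 1.22 CPM in controls and 22.3 ± 0.85 CPM in the model, and Trem2, a lipid-sensing receptor of microglia, 12.3 ± 2.07 and 36.3 ± 17.5 CPM. C1qc, a chain of complement C1q, measured 25.9 ± 11.3 and 55.7 ± 15.6 CPM. As a mean log2 difference from the control mean, the list lay at 1.65 in model A and 0.45 in model B, and its call was lost without model A (adjusted p = 0.39). Such a level, given in this comparison for complement and each list that passed, is also the group difference without the other model sample. All 13 complement genes were higher in estimate without passing as a list (camera adjusted p = 0.0645). The complement list lay at 1.61 in model A but at -0.27 in model B, about the lowest control (-0.28), and its direction turned without model A (adjusted p = 0.875). Among them C3, the central complement protein, reached 84.9 CPM in model A and 12.1 CPM in model B against 6.49 ± 2.21 CPM in controls, and C2 52.7 and 16.1 CPM against 11.8 ± 2.71 CPM.

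Interferon-stimulated genes were higher in estimate for 17 of 19 members, with a median log2 fold change of 0.98 (camera adjusted p = 0.000503, and adjusted p = 0.977 with an estimated correlation). No member passed over all genes, and 2 rose when adjusted over the list alone. These were Ifit3 and Ifit2, which encode interferon-induced proteins that bind foreign RNA. Ifit3 went from 2.83 ± 0.83 to 9.77 ± 3.21 CPM (adjusted p = 0.14 over all genes) and Ifit2 from 6.14 ± 0.643 to 12.1 ± 1.27 CPM (adjusted p = 0.146). Mx2, an antiviral GTPase, measured 55.8 ± 8.77 CPM in controls and 120.5 ± 58.4 CPM in the model. Model A held this list at 1.51 and model B at 0.10, inside the control range of -0.43 to 0.42. Its call was lost without model A (adjusted p = 0.475) and with a stricter filter on low counts (0.0636).

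Axon growth and regeneration genes were higher in estimate for 14 of 16 members (median log2 fold change 0.63, camera adjusted p = 0.0111, and adjusted p = 0.977 with an estimated correlation). Klf6 and Gap43 rose when adjusted over the list alone. Klf6, a transcription factor linked to axon regrowth, measured 29.7 ± 1.58 CPM in controls and 59.5 ± 0.594 CPM in the model (adjusted p = 0.108 over all genes). Gap43, a growth cone protein, measured 155 ± 25.6 and 433 ± 51.2 CPM (log2 fold change 1.49, SE 0.26, adjusted p = 0.115). The list lay at 0.90 in model A and 0.51 in model B, and its call was lost without model A (adjusted p = 0.39).

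The list of GABAergic neuron genes passed with a positive direction (camera adjusted p = 0.0325, and adjusted p = 0.977 with an estimated correlation), with 7 of 10 members higher in estimate. Its median log2 fold change was 1.03 but its mean only 0.05, because of Gad2, named for this after its values were seen. Gad2 was at 0 CPM in both model samples and at 3.12, 0 and 0.183 CPM in control A, B and C, so its fitted fold change is not a measured size. Whether values of 0 CPM stand for absent expression or for how reads were counted was not tested. This was the list that also passed the directional fry test (adjusted p = 0.00273). Sst, the neuropeptide somatostatin, and Lhx6, a transcription factor of cortical interneurons, rose when adjusted over the list alone. Sst went from 105 ± 16.4 to 277 ± 31 CPM (log2 fold change 1.40, SE 0.18, adjusted p = 0.0865 over all genes) and Lhx6 from 9.09 ± 0.469 to 18 ± 3.03 CPM. Cck, a peptide of interneurons and of some pyramidal cells, measured 327 ± 51.4 and 899 ± 425 CPM. The mean level of this list, which includes Gad2, was 0.49 in model A and 0.12 in model B. The latter was inside the control range of -0.23 to 0.30. The difference of 0.30 between the group means was 0.19 without control B. The median of the list's members lay at 0.84 in model A and 0.59 in model B, against -0.10 to 0.07 in controls. The camera call was lost without model A (adjusted p = 0.39), control B (0.0735) or electroacupuncture B (0.0604), and with total counts in place of TMM (0.0921).

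Myelin and oligodendrocyte genes were lower in estimate for 11 of 12 members (median log2 fold change -0.73, camera adjusted p = 0.00165, and adjusted p = 0.977 with an estimated correlation), and none passed singly. Ugt8, an enzyme of myelin lipid synthesis, measured 133 ± 35.3 CPM in controls and 59.2 ± 26.9 CPM in the model, Cldn11, a tight junction protein of myelin, 561 ± 227 and 245 ± 152 CPM, and Mog, a myelin surface protein, 176 ± 50.4 and 104 ± 32.4 CPM. The list lay at -1.16 in model B and -0.30 in model A, inside the control range of -0.38 to 0.37. Without model B the call was lost (adjusted p = 0.171).

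Postsynaptic density and glutamate receptor genes were lower in estimate for 16 of 22 members (median log2 fold change -0.32, camera adjusted p = 0.0111, and adjusted p = 0.977 with an estimated correlation). Of these, 4 fell when adjusted over the list alone and none over all genes. Gria1, an AMPA receptor subunit, was among them and measured 57.2 ± 5.47 CPM in controls and 21 ± 3.36 CPM in the model (log2 fold change -1.44, SE 0.35, adjusted p = 0.175 over all genes), as was Camk2b, another chain of calcium/calmodulin-dependent kinase II, at 1369 ± 142 and 585 ± 170 CPM. So was Cacng8, a regulator of AMPA receptors named after its values were seen, at 94.8 ± 8.1 and 27.9 ± 9.5 CPM. The hippocampal list was lower in the same 2 model samples (-1.59 and -1.59). The median of the postsynaptic list's members lay at -0.71 in model A and at -0.003 in model B, and their mean at -0.83 and -0.35, so that the mean difference of -0.59 was -0.35 without model A and -0.39 without control A. The call was lost without model A (adjusted p = 0.878) or control A (0.0818) and with the stricter filter (0.0651). Nuclear genes of oxidative phosphorylation were lower in estimate for 16 of 18 members by a small median of -0.19 (camera adjusted p = 0.02, and adjusted p = 0.977 with an estimated correlation). Uqcrc2, a core protein of complex III, measured 218 ± 10.4 CPM in controls and 148 ± 10.6 CPM in the model, cytochrome c (Cycs) 342 ± 39.3 and 224 ± 42.2 CPM, and Cox5a, a subunit of complex IV, 333 ± 31.1 and 234 ± 13.1 CPM. Levels were -0.34 in model A and -0.10 in model B. This call was lost without model A (adjusted p = 0.74) or control B (0.0528), with total counts (0.0663), with the stricter filter (0.0736) and on quantile-normalized values (0.319).

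Reactive astrocyte genes did not pass (camera adjusted p = 0.782), with 12 of 18 higher in estimate. Serpina3n, a protease inhibitor usually counted among reactive astrocyte genes, went the other way, at 0.21 and 0 CPM in model A and B against 8.39 ± 3.7 CPM in controls (adjusted p = 0.17 over all genes), and it fell when adjusted over the list alone. Steap4, a metalloreductase, measured 1.13 and 3.01 CPM in model A and B against 0.09 to 0.46 CPM in controls, and Stat3, a transcription factor of cytokine signalling, 40.2 ± 7.36 CPM against 28.7 ± 2.06 CPM.

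Of the other lists, those closest to passing after complement were heat shock and the unfolded protein response (camera adjusted p = 0.0645, 10 of 15 lower in estimate). Antigen presentation, cytokines and chemokines, cell cycle, hypothalamic and thalamic neurons, GABA-A receptors and neurotrophin and plasticity signalling each had a camera adjusted p of 0.261, striatal medium spiny neurons and immediate early genes 0.273 and ribosomal proteins 0.32. Extracellular matrix and scar genes were at 0.59, choroid plexus and ependyma at 0.61, endothelium at 0.661, astrocyte identity at 0.769, blood and red cells at 0.843, presynaptic release at 0.879 and mural cells and fibroblasts at 0.926. Pan-neuronal genes, glutamatergic neurons, oligodendrocyte precursors, apoptosis and p53 targets and neutrophils and lymphocytes were each at 0.932. Median, mean and test differed in sign for pan-neuronal genes (-0.06, -0.10, up), neutrophils and lymphocytes (0.34, -0.56, down) and the extracellular matrix (0.08, 0.02, down).

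At an unadjusted p under 0.05, 1179 genes were higher and 960 lower in the model, where chance would give 774 in all. Both model samples lay outside the control range in the same direction for 37.8% of genes (20% by chance). DESeq2 on the same 8 samples called 799 genes, and edgeR called 1129 when all 11 columns entered as separate libraries, both including Camk2d. Camk2d lost its call without control A (adjusted p = 0.358), control B (0.309), control C (0.223), model B (0.108) or electroacupuncture B (0.075) and with total counts (0.0765). In these 6 fits its log2 fold change was 2.95 to 3.18, with an SE of 0.25 to 0.30 in place of 0.23, so the size of change was similar. The larger SE alone does not account for the lost calls. With the stricter filter the call held at an SE of 0.25 (edgeR adjusted p = 0.0289). The count of called genes was 356 without model A and 565 without electroacupuncture A.

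**Figure D2:**
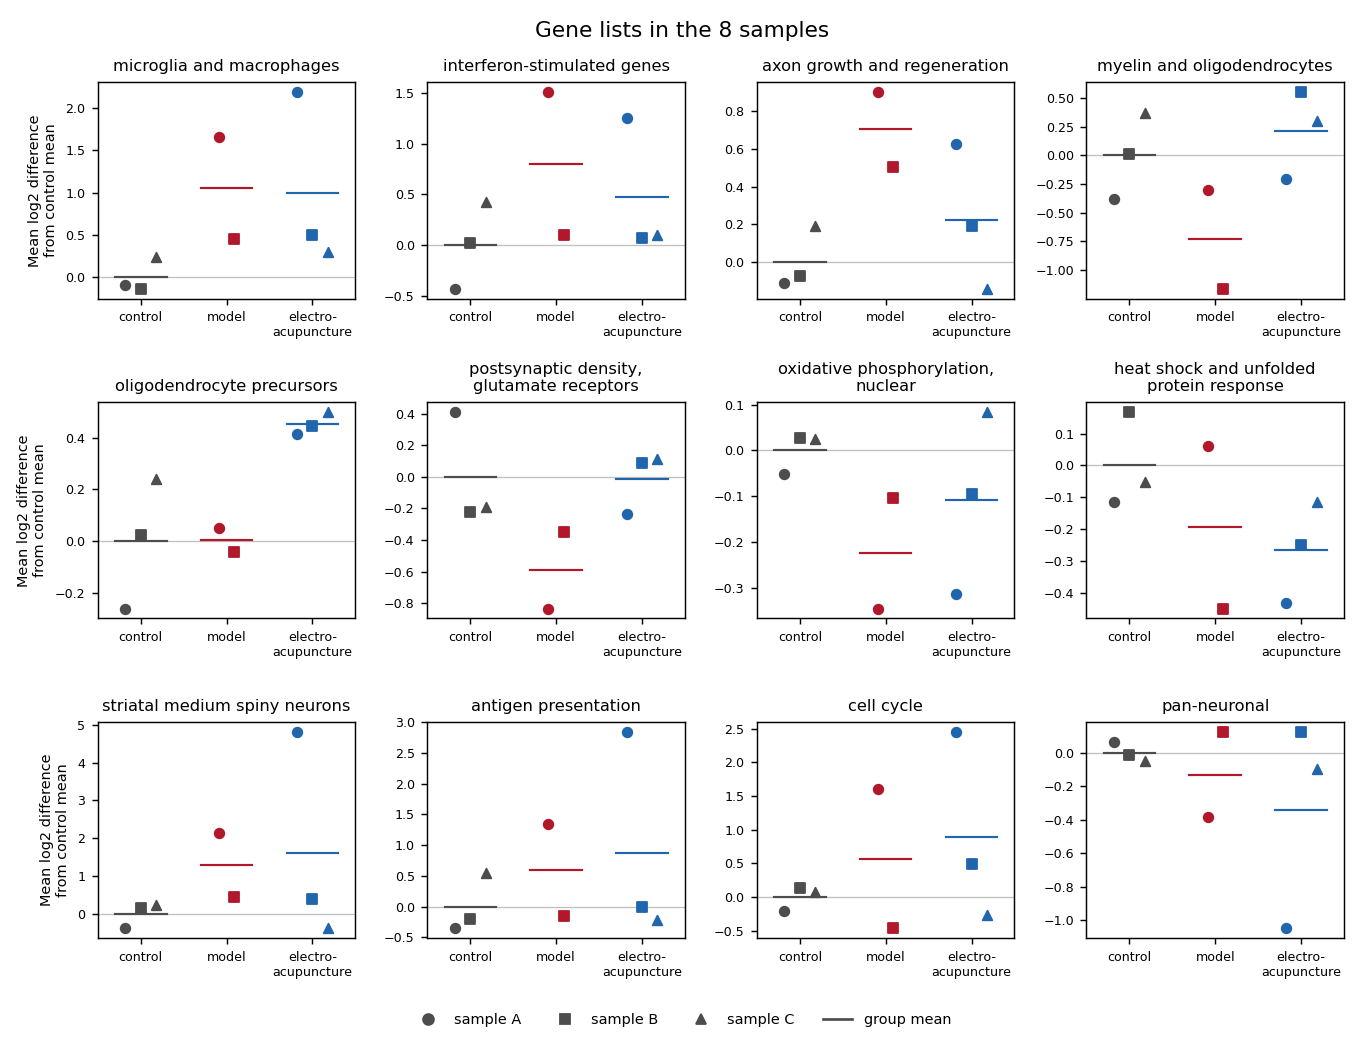
Each point is 1 sample, and the vertical axis gives the mean log2 difference of a list's genes from the control mean, with a line at each group's mean. Model A and electroacupuncture A stand apart in the lists of microglia (1.65 and 2.19), striatal neurons (2.14 and 4.82) and antigen presentation (1.34 and 2.84).

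The second comparison, electroacupuncture against model, asks what the treatment changed after the operation. Myelin and oligodendrocyte genes ranked higher with electroacupuncture, in estimate for all 12 members, and 7 had every electroacupuncture sample above both model samples. The median log2 fold change was 1.05 (camera adjusted p = 6.65e-05, but adjusted p = 0.99 with an estimated correlation). Mag, a myelin adhesion protein, measured 136 ± 50.3 CPM (SD, n = 2) in the model and 342 ± 74.8 CPM (SD, n = 3) with electroacupuncture, and Mog 104 ± 32.4 and 217 ± 59.8 CPM. Cldn11 measured 245 ± 152 and 682 ± 209 CPM. The list's call held in each of the 8 fits that left out 1 sample, with a highest adjusted p of 0.0272 without model B. Its size rested on model B: the list lay at -0.30 and -1.16 in model A and B and at -0.21, 0.55 and 0.30 in electroacupuncture A, B and C, and the difference of 0.95 between the group means was 0.52 without model B. No single gene passed, over all genes or over the myelin list alone.

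Oligodendrocyte precursor genes pointed the same way without passing as a list (camera adjusted p = 0.0696, 7 of 8 higher in estimate). Gpr17, a receptor of precursors about to differentiate, and Olig2, a transcription factor of the lineage, rose when adjusted over the list alone. Gpr17 measured 4.46 ± 0.737 CPM in the model and 10.7 ± 2.12 CPM with electroacupuncture (log2 fold change 1.26, SE 0.27, adjusted p = 0.144 over all genes), and Olig2 41.6 ± 1.21 and 68.7 ± 5.44 CPM (0.72, SE 0.19, adjusted p = 0.181). Olig1, its close relative, measured 166 ± 11.8 and 239 ± 28.9 CPM.

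Among synaptic genes, the postsynaptic density list did not pass (camera adjusted p = 0.0696, 14 of 22 higher in estimate). Gria1 measured 21 ± 3.36 CPM in the model and 53.4 ± 21.8 CPM with electroacupuncture, and the NMDA receptor subunit Grin2a 1.34 ± 1.51 and 9.86 ± 6.91 CPM. In electroacupuncture A, which shared the low hippocampal markers of the model samples, Gria1 stood at 29.9 CPM against 73 and 57.2 CPM in electroacupuncture B and C. Presynaptic release genes did not pass (camera adjusted p = 0.14, 15 of 20 lower in estimate). Stx1a, a syntaxin of vesicle fusion, measured 138 and 434 CPM in model A and B against 68.8 ± 18.2 CPM with electroacupuncture. Pclo, an active zone scaffold, measured 123 and 145 CPM against 44 to 117 CPM, and Sv2a, a synaptic vesicle protein, 355 and 463 CPM against 156 to 391 CPM.

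Axon growth genes did not pass either (camera adjusted p = 0.0848, 11 of 16 lower in estimate), but Klf6 and Gap43 fell when adjusted over the list alone. Klf6 measured 59.5 ± 0.594 CPM in the model and 28.3 ± 4.62 CPM with electroacupuncture (log2 fold change -1.07, SE 0.16, adjusted p = 0.135 over all genes), and Gap43 433 ± 51.2 and 190 ± 51.1 CPM (-1.19, SE 0.26, adjusted p = 0.15). Lgals1, a lectin of injured nerve, measured 21.6 and 13 CPM in model A and B and 8.88 to 14.1 CPM with electroacupuncture. Immediate early genes were higher in estimate for 16 of 18 members without passing (camera adjusted p = 0.14). Nr4a3 measured 12.8 and 11 CPM in model A and B and 14.4 to 55.5 CPM with electroacupuncture, Egr1 10.2 and 18.1 CPM and 15.2 to 48.9 CPM, and Fosl2 0.643 and 1.04 CPM and 1.37 to 2.04 CPM. Interferon-stimulated genes were lower in estimate for 16 of 19 members without passing (camera adjusted p = 0.152), with Mx2 at 120.5 ± 58.4 and 72.1 ± 24.2 CPM, Ifit2 at 12.1 ± 1.27 and 8.77 ± 0.363 CPM and Oasl2 at 63.2 and 23.2 CPM in model A and B against 12.2 to 33.1 CPM. GABAergic neuron genes passed the directional fry test as lower (adjusted p = 0.014) but not camera (adjusted p = 0.153), and their median of -0.48 and mean of 0.55 differed in sign, the mean again because of Gad2, at 36.3, 0 and 6.22 CPM in electroacupuncture A, B and C. Sst fell when adjusted over the list alone, from 277 ± 31 to 137 ± 13.6 CPM. Lhx6 measured 18 ± 3.03 and 11.4 ± 1.41 CPM and Cck 899 ± 425 and 261 ± 161 CPM. Among lists that did not pass, median, mean and test also differed in sign for microglia (0.14, 0.10, down), reactive astrocytes (-0.10, 0.21, down), mural cells (-0.14, -0.06, up), choroid plexus (0.34, 0.24, down), blood (0.06, -0.09, down), neutrophils and lymphocytes (-0.17, 0.69, down), cytokines (0.16, -0.52, down) and neurotrophin signalling (0.10, 0.16, down).

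With edgeR, 0 genes passed at an adjusted p under 0.05, the smallest being Camk2d at 0.123 (143 ± 15.2 to 27.7 ± 7.04 CPM, log2 fold change -2.37, SE 0.23). At an unadjusted p under 0.05, 975 genes were higher and 1112 lower, against 774 by chance, and all electroacupuncture samples lay on 1 side of both model samples for 24.6% of genes (20% by chance). DESeq2 called 705 genes, edgeR 1666 with all 11 columns as separate libraries, 308 without model A and 278 without electroacupuncture A.

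**Figure D3:**
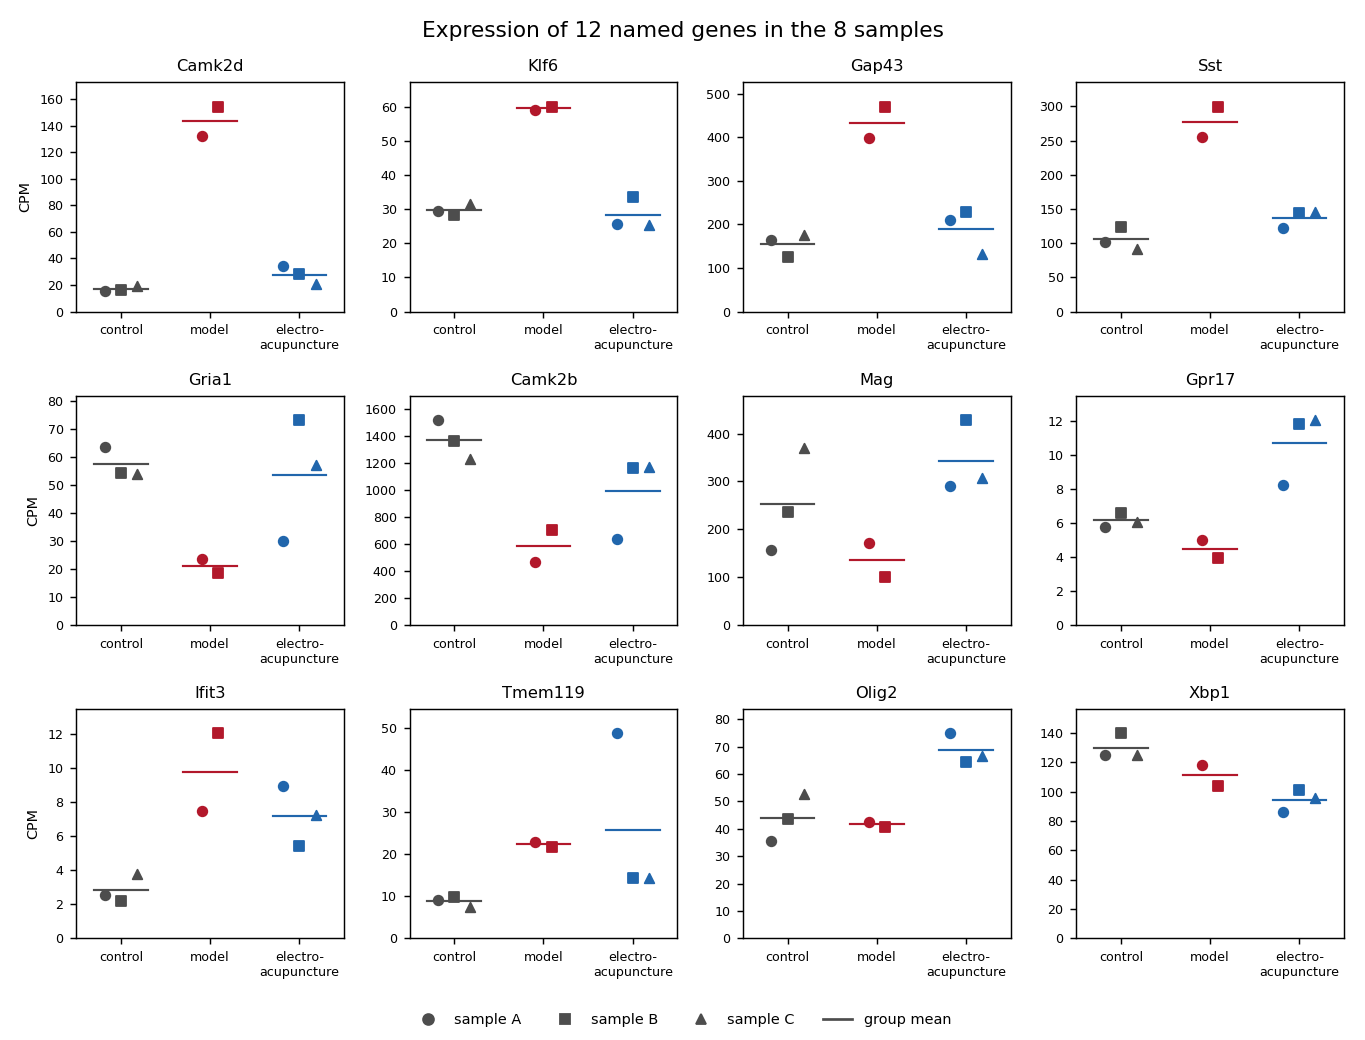
Each point is 1 sample, in TMM-scaled CPM on an axis that starts at 0, with a line at each group's mean. Camk2d stands at 133 and 154 CPM in the model samples and at 15.1 to 34.5 CPM in the other 6, and Gpr17 and Olig2 are highest in the 3 electroacupuncture samples.

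The third question is whether genes moved by the operation moved back with treatment. No gene was called in both comparisons by edgeR. At an unadjusted p under 0.05 in both, 713 genes were higher in the model and lower with electroacupuncture and 554 the reverse, where independent lists would share 84.7 and 60.4, and 0 genes moved the same way. Klf6, Gap43, Sst and Camk2d were among the former and Gria1 among the latter. Both comparisons share the model samples, which alone produces opposed changes. Independent lists are therefore not a fair reference for the 713 and 554 genes, and no such count was simulated. The correlation of the log2 fold changes across genes was -0.717, against -0.605 (range -0.643 to -0.56) in 50 simulations with unchanged groups, and the covariance was -0.498 against -0.223. Both excesses were smaller than the spread between samples: the jackknife SE over samples left out in turn was 0.299 for the correlation and 0.813 for the covariance. The correlation was -0.551 without electroacupuncture B, -0.578 without control A and -0.602 without electroacupuncture C, and the covariance -1.394 without model A and -0.756 without model B. Splitting the model, with A in 1 comparison and B in the other, gave correlations of -0.138 and -0.254. Since the model holds only 2 samples, each part of the split is 1 sample. The split comparisons share no sample, so -0.605 is not their reference, and none was simulated for them. The simulations held the shared model samples but drew genes independently, so part of the excess may still come from the shared samples. DESeq2 called 421 opposed genes and the fit of all 11 columns 808. The number was 287 without model A and 248 without electroacupuncture A.

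The fourth comparison, electroacupuncture against control, shows how far treated animals stood from controls. Oligodendrocyte precursor genes were higher in estimate for all 8 members (median log2 fold change 0.45, camera adjusted p = 0.000583, and adjusted p = 0.728 with an estimated correlation). Olig2, Gpr17 and Pdgfra rose when adjusted over the list alone. Olig2 measured 44 ± 8.75 CPM (SD, n = 3) in controls and 68.7 ± 5.44 CPM (SD, n = 3) with electroacupuncture, Gpr17 6.14 ± 0.417 and 10.7 ± 2.12 CPM, and Pdgfra, the growth factor receptor of precursors, 22.1 ± 3.4 and 34.3 ± 3.77 CPM. The list lay between 0.41 and 0.50 in all 3 electroacupuncture samples and between -0.26 and 0.24 in the controls.

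Heat shock and unfolded protein response genes ranked lower, in estimate for 12 of 15 members (median log2 fold change -0.29, camera adjusted p = 0.00129, and adjusted p = 0.728 with an estimated correlation). No member passed singly. The list lay at -0.432, -0.249 and -0.116 in electroacupuncture A, B and C and between -0.115 and 0.168 in the controls. Electroacupuncture C was thus about level with the lowest control. The difference of -0.27 between the group means was -0.18 without electroacupuncture A and also without control B. Xbp1, a transcription factor of the unfolded protein response, measured 130 ± 8.45 CPM in controls and 94.4 ± 7.51 CPM with electroacupuncture, the endoplasmic reticulum chaperone Hspa5 376 ± 44.9 and 260 ± 15.4 CPM, and the cytosolic chaperone Hspa8 1920 ± 106 and 1457 ± 271 CPM. Microglia genes ranked higher, in estimate for all 16 members (median 1.19, camera adjusted p = 1.46e-06, and adjusted p = 0.728 with an estimated correlation). Only 2 of these members had every electroacupuncture sample above all controls. The list lay at 2.19 in electroacupuncture A and at 0.50 and 0.30 in B and C, above the control range of -0.14 to 0.24. Tmem119 measured 48.7, 14.3 and 14.2 CPM in electroacupuncture A, B and C against 8.79 ± 1.22 CPM in controls, Laptm5, a lysosomal protein of white blood cells, 103, 32.9 and 25 CPM against 20.7 ± 4.4 CPM, and the fractalkine receptor Cx3cr1 14.7, 9.27 and 4.75 CPM against 4.5 ± 0.634 CPM. These 3 list calls held in each of the 8 fits that left out 1 sample, but the mean difference of the microglia list was 0.40 without electroacupuncture A and 1 with all samples.

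A further 8 lists passed camera and each lost its call without electroacupuncture A, and none passed with an estimated correlation (adjusted p = 0.728 for each). Higher were striatal medium spiny neurons (adjusted p = 0.00273, and 0.792 without electroacupuncture A), cell cycle (0.00375, and 0.792), interferon-stimulated genes (0.00129, and 0.128), antigen presentation (0.0155, and 0.792) and astrocyte identity (0.0285, and 0.115). Lower were neurotrophin and plasticity signalling (0.0124, and 0.282), pan-neuronal genes (0.0197, and 0.962) and presynaptic release (0.0259, and 0.962). Without electroacupuncture A the mean difference from controls moved from 1.61 to 0.01 for the striatal list, 0.89 to 0.11 for cell cycle, 0.47 to 0.08 for interferon-stimulated genes, 0.87 to -0.12 for antigen presentation, 0.20 to 0.11 for astrocyte identity, -0.61 to -0.11 for neurotrophin signalling, -0.34 to 0.01 for pan-neuronal genes and -0.32 to 0.02 for presynaptic release. It was larger without electroacupuncture C for the striatal list (2.60), cell cycle (1.47) and antigen presentation (1.41), and without electroacupuncture B for antigen presentation (1.31), pan-neuronal genes (-0.57) and presynaptic release (-0.59). For interferon-stimulated genes it was 0.26 without control A. Electroacupuncture A held 151 CPM of the dopamine receptor gene Drd2, 1250 CPM of the opioid peptide gene Penk and 126 CPM of Tac1, the substance P precursor, where no other sample exceeded 13.3, 168 and 21.2 CPM. Its class II antigen presentation genes Cd74, RT1-Da and RT1-Db1 stood at 831, 145 and 118 CPM, where no other sample exceeded 90, 10.3 and 4.72 CPM. The proliferation genes Top2a, Rrm2 and Pcna stood at 35.7, 24.7 and 55.9 CPM there, where no other sample exceeded 9.06, 7.93 and 34.2 CPM. In the astrocyte list Fgfr3 measured 44.5 ± 2.65 CPM in controls and 62.8 ± 13.8 CPM with electroacupuncture, Slc1a3, a glutamate transporter, 202 ± 16.4 and 281 ± 72.9 CPM, and S100b 1487 ± 93 and 2061 ± 472 CPM. In the interferon list, Ifit3 measured 2.83 ± 0.83 and 7.22 ± 1.75 CPM and Ifit2 6.14 ± 0.643 and 8.77 ± 0.363 CPM, with all 3 electroacupuncture samples above all controls, as was Mx1 at 2.72 to 11.8 CPM against 0.46 to 2.1 CPM. On quantile-normalized values the 3 lower calls were lost (neurotrophin signalling at adjusted p = 0.0626, pan-neuronal genes at 0.125 and presynaptic release at 0.118), and all lists past the threshold were split into 10 higher and 1 lower, against 7 and 4 with TMM and 6 and 6 with total counts. With the stricter filter 3 higher and 4 lower lists passed. The calls of striatal neurons (adjusted p = 0.109), interferon-stimulated genes (0.0613) and antigen presentation (0.066) were lost there, the last also with total counts (0.0511). A further higher list was not tested with that filter, which left it with fewer than 4 members. With all 11 columns as separate libraries antigen presentation (0.0728), astrocyte identity (0.0713), pan-neuronal genes (0.145) and presynaptic release (0.193) were lost. The astrocyte call was also lost without control B (adjusted p = 0.0641), control C (0.0574) or electroacupuncture C (0.131).

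In the lower lists, Ntrk3, a neurotrophin receptor, measured 72.6 CPM in electroacupuncture A and 138 and 126 CPM in B and C, against 135 to 180 CPM in controls and Adcy1, an adenylyl cyclase, 166, 703 and 669 CPM against 725 to 1000 CPM. Elavl3 and Stmn2, neuronal RNA-binding and cytoskeletal proteins, were estimated at -0.28 (SE 0.20) and -0.35 (SE 0.32) on the log2 scale and Gap43 at 0.29 (SE 0.24). Among presynaptic genes, Unc13a and Pclo were estimated at -0.40 (SE 0.23) and -0.47 (SE 0.32) and Syngr1 at 0.36 (SE 0.31). Without control A, 4 of the 8 lists that depended on electroacupuncture A were also lost: neurotrophin signalling (adjusted p = 0.0919), pan-neuronal (0.0919), presynaptic release (0.139) and antigen presentation (0.0956). Presynaptic release was lost as well without control C (0.0527) or electroacupuncture C (0.0516), and antigen presentation without control B (0.0554).

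No gene passed in this comparison with edgeR (smallest adjusted p = 0.52). At an unadjusted p under 0.05, 419 genes were higher and 148 lower, fewer than the 774 chance would give, and the groups were apart for 10.9% of genes (10% by chance). DESeq2 called 1 gene and the fit of all 11 columns 0. The median, mean and test of neutrophils and lymphocytes differed in sign (0.24, 0.13, down).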

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

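The tests on all 11 columns, with or without the column number as block, on single columns or means of pairs, of gene lists and their levels with 1 sample left out and of the covariance were chosen after the results were seen. The count of genes called between model and control moved from 1 to 799 with DESeq2, 294 with only the 2 groups compared, 33 at an adjusted p under 0.1, 0 with total counts and 1129 with all 11 columns. For electroacupuncture against model it moved from 0 to 705 with DESeq2 and 1666 with all 11 columns, and for opposed genes from 0 to 421 and 808. For electroacupuncture against control DESeq2 called 1 gene and all others 0. Of the 799 and 705 DESeq2 calls, 704 and 659 were also called with all 11 columns. With 1 sample left out, the counts ranged from 0 to 565 (model against control), 0 to 308 (electroacupuncture against model), 0 to 0 (electroacupuncture against control) and 0 to 287 (opposed genes), and the correlation of the 2 log2 fold changes from -0.87 to -0.551. An arm left with 1 sample was assumed to vary like the other groups. With DESeq2's size factors in edgeR the counts were 1, 0 and 0 with 0 opposed, so scaling does not account for the larger DESeq2 counts. Other causes of these differences were not tested.

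Pairing by sample title was not possible because the columns carry no titles, so the column number stands in for it here. With the column number of all 11 columns as replicate block, 471, 876 and 0 genes were called in the 3 comparisons and 317 were opposed, with 11, 6 and 12 gene lists past the threshold. In electroacupuncture against control the calls of astrocyte identity (adjusted p = 0.0671), pan-neuronal genes (0.0533) and presynaptic release (0.0893) were lost. Of 10 same-numbered column pairs from different groups, 7 had deviations that correlated above 0.1 (range -0.164 to 0.19, median 0.138 against -0.018 for other pairs). Pairing was taken to need all pairs above 0.1, so the numbers were not used to pair samples. Not every column correlated best with its own number, such as control 1 with model 1 (-0.164) and with model 3 (0.168). Between control and electroacupuncture the same-numbered pairs 1, 2 and 3 all lay above 0.1 (0.145, 0.157 and 0.19). Each of these control columns correlated more with an electroacupuncture column of another number (0.296, 0.177 and 0.216). For control 2 and 3 that column belongs to the same merged sample, electroacupuncture B, as the same-numbered column. Those 2 differences therefore say nothing on pairing, and only control 1 (0.296 with electroacupuncture 4) compares different samples.

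With camera, 7, 1 and 11 gene lists passed (model against control, electroacupuncture against model, electroacupuncture against control). The numbers were 0, 0 and 0 with an estimated correlation, 1, 1 and 0 with directional fry, and 1, 4 and 1 with mixed fry. They need not be the same lists: in electroacupuncture against model directional fry passed GABAergic neurons (adjusted p = 0.014) and not myelin (0.519). Total counts gave 5, 3 and 12, quantile normalization 6, 1 and 11, no filter 8, 3 and 11, the stricter filter 4, 1 and 7, and all 11 columns 7, 4 and 7. Quantile normalization added myelin (adjusted p = 0.0163), endothelium (0.0495) and ribosomal proteins (0.0163) in electroacupuncture against control. With 1 sample left out the numbers ranged from 2 to 16, 1 to 14 and 7 to 17. Total counts moved the median log2 fold change of all genes between model and control from 0.02 to 0.13.

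Over 85 pairs of named gene and comparison and the alternatives run for each, 1659 values kept their side of the threshold and direction, 94 passed it newly, 6 lost it (all Camk2d) and 2 changed sign. The latter were Cfd, a complement factor, in model against control at -0.09 without model A (-0.09 to 2.38 with 1 sample left out), and RT1-Da in electroacupuncture against control at -0.24 without electroacupuncture A (-0.24 to 6.12). The pseudocount alternative did not apply to counts. Depth limits genes under about 1 CPM, and the number of samples limits changes near 2-fold.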

Other observations

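All tests here were chosen after the results were seen, except those of on-or-off genes over all genes, of the sum of lymphocyte markers and of other splits of the samples.

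Blood and choroid plexus genes differed between single samples without following the groups. Hbb, a hemoglobin chain, measured 26.7 CPM in electroacupuncture C and 343 to 1792 CPM in the other 7 samples, and Alas2, the heme synthesis enzyme of red cells, 0.84 CPM against 7.29 to 35.8 CPM. Ttr, the transthyretin gene of choroid plexus, measured 1344 CPM in control C and 3.36 to 86.4 CPM in the others. These genes were named after their values were seen.

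The near-identical columns were tested for being repeat measurements of 1 RNA. Genes on (at least 5 CPM) in some and off (at most 0.5 CPM) in other columns outside the pair disagreed in 1.72% to 3.99% of cases within the 3 near-identical pairs and in 3.19% to 15.9% within the 12 other pairs of 1 group, a ratio of highest to lowest of 1.25 that by the bound set beforehand goes against repeat measurement. That bound is not used here because all 41 disagreements within near-identical pairs fell on genes with fractional estimates, which can differ between repeats of 1 RNA if reads are assigned among gene copies. Among genes with whole counts in every column, a subset chosen after that result, 0% of 624 cases disagreed within near-identical pairs and 1.29% to 16.6% within the others. Since the pairs were picked for differing little, also on whole counts, this low share decides nothing, and 1 RNA measured again and separate animals with tissue this alike cannot be told apart.

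The low hippocampal genes in both model samples and electroacupuncture A may reflect which brain regions were in the tissue, a hypothesis. In model B the pan-neuronal list lay at 0.122 with 5 of 13 members lower (Nefl at -0.88), and without Gap43, also an axon growth gene, at 0, inside the control range of -0.07 to 0.06, so members that go both ways leave a loss of neurons there open. In model A and electroacupuncture A the list lay at -0.381 and -1.05 while striatal neuron genes were higher, and in all 3 samples a loss of neurons and a different tissue cannot be told apart. The neocortex list lay at 1.142 or above in both model samples, as other regions would need, but also at 0.58 in electroacupuncture B, whose hippocampal list lay near the controls (-0.05). The striatal list lay at 4.818 in electroacupuncture A, with Ppp1r1b at 2067 CPM against 94.2 to 97.5 CPM in controls, and an effect of the operation on region-specific genes stays open as untested.

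The class II antigen presentation genes of electroacupuncture A had a median log2 difference of 5.94 from the control mean, and 5 of 7 exceeded the highest of 16 microglia genes (3.94). This argues against more microglia of the kind the controls hold as the whole cause, though the test was first set on the lowest class II gene, RT1-DMa at 0.82, which lies below all microglia genes, and was moved to the median after that value was seen. Lymphocytes or neutrophils were set to need their 16 markers above the highest other sample, model A, by as large a factor as Cd74. That factor was 9.23 with TMM and 9.74 with total counts. The marker sums were 107 against 109 CPM (0.99 times) and 121 against 116 CPM (1.04 times), so the sum did not rise with Cd74. With total counts it still lay above all other samples, outside the range set beforehand as going against these cells. Cd4 made up 81.5 CPM of the TMM-scaled sum and 79.8 CPM in model A, so a small number of added cells could leave the sum almost unmoved. The test therefore cannot decide, and lymphocytes, neutrophils and cells that carry class II genes without these markers stay open. Electroacupuncture B and C, at -0.01 and -0.22 in the antigen presentation list, did not share the pattern, so it may belong to that sample rather than to the treatment.

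The 3 control and 3 electroacupuncture samples allow 10 splits, too few for a share under 0.05. The real split called 0 genes and the highest other 59; all 10 splits reach a count of 0 by construction, so this comparison says nothing. At an unadjusted p under 0.05 the real split gave 567 genes and the highest other 1261 (4 splits gave as many), and for gene lists 11 and 21 (8 gave as many). The split that called 59 genes set control A with electroacupuncture A and C against the others, but gave 339 genes at an unadjusted p under 0.05, fewer than the real split, so the 2 counts do not point the same way.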
